A study of Saccharomyces cerevisiae with 72 samples.

How the data were processed

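The samples are 72 Affymetrix yeast arrays of Saccharomyces cerevisiae: 6 genotypes (wild type, which per the labels is strain KY652, and gcn2, gcn4, gln3, gcn2 gln3 and gcn4 gln3), 3 treatments and 4 replicates per group. Per the labels' protocols, cells grew in synthetic medium with 2% dextrose, 0.5% ammonium sulfate and all amino acids but histidine, and were treated for 1 h with 10 mM 3-aminotriazole (3-AT), 200 nM rapamycin or nothing. Per the same protocols, total RNA came from hot phenol extraction and 5 ug was made into biotinylated cRNA. Whether replicates are separate cultures is not stated, so p-values measure only the spread between these samples.

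The deposited values are linear intensity (signal) for 9335 probe sets on each array. Per the submitters' processing notes, the authors made them with GCOS and MAS5, whose versions are not given in the sources used here. In the deposited table the mean signal of each array after trimming 2% at each end lies at 999 to 1000, so the arrays had been scaled to a common mean. Before any other step the median signal of the arrays ran from 259 to 400 and its 30th percentile from 66.0 to 137. No 2 arrays are copies, since the highest correlation between 2 arrays was 0.992. All 72 columns were used and none was left out of the main fit.

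Signals were raised to a floor of 16.3, the 10th percentile of all probe set values, and log2 transformed with no further scaling. The plan named the median signal of Schizosaccharomyces pombe probe sets as the floor, with this percentile as the fallback, and the table holds no such probe sets. The 60 control probe sets were left out. Of the others, 6504 read 1 gene each, 328 read several and 2443 have no named gene in the reference used. Where a gene has several probe sets (315 of 5656 genes), the one with the highest mean was kept, which left 8427. A probe set was tested if its signal lay above background, the 30th percentile of its array, on at least 4 of 72 arrays. That left 6869 probe sets, for 5409 named genes.

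Each probe set was fitted with 18 group means in limma 3.58.1 (R 4.3.3, data.table in version 1.17.8) with 54 residual degrees of freedom, and the variances were moderated over probe sets (prior degrees of freedom 4.53). There were 32 contrasts. They were the response of each genotype to each drug, the difference of each mutant's response from that of wild type, and each mutant against wild type without treatment. The others were 3-AT against rapamycin in wild type, the gcn2 response against the gcn4 response, and the interaction of losing GCN4 and GLN3 in each response. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and passing or being called means an adjusted p under 0.05. A difference of responses is the mutant's log2 change minus that of wild type, so it is negative where the mutant rose less or fell more. Array reading and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

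Where no array of 1 of the groups compared lay above background, a bound is printed in place of a ratio. It is the fold change with each array of the dim group set to its own background, and is written as at least so many fold.

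The 32 gene lists were written from general knowledge of yeast before the data were examined, as were the design and the contrasts. They cover biosynthesis of histidine, arginine and lysine, of branched-chain and aromatic amino acids, of the aspartate family with serine and glycine, of purines with one-carbon metabolism, and of vitamins and cofactors. They also cover sulfur assimilation and methionine, ammonia assimilation, aminoacyl-tRNA synthetases, permeases and catabolic enzymes under nitrogen catabolite repression, regulators of nitrogen and amino acid control, vacuolar proteases, autophagy, and the retrograde pathway with the citrate cycle. The others are cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, RNA polymerase I and III subunits, general stress, oxidative stress, heat shock protein folding, the proteasome, G1/S and G2/M genes, histones, glycolysis, phosphate and iron starvation, MATa-specific and MATalpha-specific genes, and auxotrophic markers. Of 137 cytosolic ribosomal protein genes 80 have a probe set of their own and 54 are read only together with a near-identical copy, so those 54 were not tested. Each list was tested with limma's camera and an estimated correlation between genes, with p-values adjusted over the 32 lists within a contrast. The count of members that passed over all probe sets is printed beside the count with p-values adjusted over the list alone.

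Genes named in the text were chosen by a rule written before the data were examined. The rule takes the 3 deleted genes, the largest rises and falls of each contrast among probe sets that passed, any member of a list of up to 25 genes, and for longer lists the members with the smallest adjusted p or the largest change. It adds a fixed set of well-known target genes, given whether or not they passed.

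Replicate numbers are shared by all groups. Same-numbered arrays deviated together (every same-number correlation of deviations from the group means over 0.1) in 9 of 18 comparisons of 2 groups, and of 144 arrays set against the other group 103 correlated best with their own number. The labels do not say what a number stands for, so this pairing comes from the data. The main fit has no block, as planned, and a fit with the replicate number as a block is an alternative.

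The alternatives chosen before the data were examined, run one at a time, were quantile normalization, centring each array on the median of probe sets above background on all arrays, 0.5 and 2 times the floor, no filter, and only the 4258 probe sets above background on all arrays. Others were the variance from only the arrays compared, an intensity trend with a robust prior, array weights, the replicate block, leaving out each array in turn, calls of at least 2-fold, each other probe set of a named gene, camera with a preset correlation of 0.01, and limma's fry. Leaving out the 3 arrays with an actin 3'/5' ratio over 10 was chosen after seeing the data. On simulated data with 200 of 6869 probe sets changed, the wild-type 3-AT contrast found 14.9% of 1.5-fold, 52.2% of 2-fold and 90.9% of 4-fold changes with 5.41% false calls. The difference of gln3 and wild-type rapamycin responses found 2.99%, 19.4% and 69.7% with 4.69% false, so 4 arrays per group miss most differences of responses under 2-fold. Camera called a list of 20 genes shifted by 0.5 in 45 of 50 draws, in which genes varied independently. That does not give its power for lists whose members vary together.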

Results

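The series holds 72 Affymetrix yeast arrays from 6 genotypes: wild type, gcn2, gcn4, gln3, gcn2 gln3 and gcn4 gln3. Each genotype was left untreated or treated for 1 h with 10 mM 3-aminotriazole (3-AT) or 200 nM rapamycin, with 4 arrays per group. 3-AT inhibits the histidine biosynthetic enzyme His3, and rapamycin inhibits the kinase complex TORC1. Gcn2 is a kinase that senses uncharged tRNA, Gcn4 is the activator of amino acid biosynthetic genes made when Gcn2 is active, and Gln3 is a GATA activator of genes under nitrogen catabolite repression. Changes below are log2 ratios ± standard error (4 arrays per group, variance pooled over groups). P-values are limma's, adjusted over 6869 probe sets.

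Actin mRNA, read by probe sets at its 3' and 5' ends, gave a 3'/5' signal ratio of 1.31 to 5.03 on 69 arrays. Its ratio was 230 and 113 on replicate 1 of gcn2 gln3 with 3-AT and with rapamycin, and 43.2 on replicate 2 of gcn4 gln3 with rapamycin. That last array also had a mean correlation of 0.542 with all other arrays, against 0.930 to 0.947 for the rest of its group. In 10 of 18 groups the highest actin ratio lay on replicate 1. The median residual standard deviation over probe sets was 0.41 with all arrays and 0.28 without these 3, so counts without them are given beside the leading counts below.

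GCN4 mRNA gave a signal of 15530.4 ± 1085 (mean ± SD) in untreated wild type and 3.85 to 86.8 on the 24 arrays of the gcn4 strains, none above background. GLN3 mRNA gave 211 ± 26.1 in untreated wild type and 0.416 to 39.4 on the 36 arrays of the gln3 strains, again none above background. The GCN2 probe set read 229 ± 26.5 in untreated wild type and 95.9 ± 19.5 in untreated gcn2 (adjusted p = 3.8e-05). Over untreated arrays it read 74.9 to 123 in the gcn2 strains and 201 to 256 in the others, so its signal was lower but not gone. In wild type, GLN3 mRNA rose by 1.76 ± 0.17 with 3-AT (adjusted p = 7.8e-13) and by 1.02 ± 0.17 with rapamycin (adjusted p = 2.2e-06). GCN4, controlled mainly by translation, changed by -0.10 ± 0.30 (adjusted p = 0.84) and 0.43 ± 0.30 (adjusted p = 0.28, 0.019 with only the arrays compared). Neither passed, but the error also pools the gcn4 arrays. The GLN3 rise with 3-AT was smaller in gcn2 than in wild type (-0.95 ± 0.24, adjusted p = 0.0098; adjusted p = 0.24 with 0.5 times the floor).

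In wild type, 3-AT raised genes of histidine, arginine and lysine biosynthesis, of sulfur assimilation and of amino acid control. Each of the 21 histidine, arginine and lysine biosynthesis genes rose (21 adjusted over the list alone, median 1.92, adjusted p = 5.5e-06). Among them were HIS5, encoding histidinol-phosphate aminotransferase (2.54 ± 0.16), HIS4, encoding a histidine enzyme with 3 activities (1.62 ± 0.47), ARG1, encoding argininosuccinate synthetase (1.93 ± 0.31), LYS1, encoding saccharopine dehydrogenase (2.39 ± 0.17), and ORT1, encoding the mitochondrial ornithine exporter (3.32 ± 0.18). ARG1 signal went from 5659 ± 337 to 21696 ± 2329.9 (mean ± SD). Of 24 sulfur assimilation and methionine genes, 19 rose and 1 fell (19 and 1 adjusted over the list alone, median 2.54, adjusted p = 0.0073), led by the homoserine acetyltransferase gene MET2 (4.14 ± 0.58), the cystathionine lyase gene STR3 (4.12 ± 0.28) and the siroheme synthesis gene MET1 (3.96 ± 0.34). SAM2, encoding an S-adenosylmethionine synthetase, was the member that fell (-1.33 ± 0.24). Among 22 regulators of nitrogen and amino acid control, 12 rose (15 adjusted over the list alone, median 0.69, adjusted p = 0.0073), UGA3, an activator of GABA genes, by 3.41 ± 0.12.

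Among named genes above background in both groups, the largest rise with 3-AT in wild type was of DIP5, encoding a permease for glutamate and aspartate (5.19 ± 0.26, adjusted p = 1.0e-24). The sulfate permease gene SUL2 rose by 4.31 ± 0.35, the vacuolar amino acid transporter gene RTC2 by 4.47 ± 0.38, and ARO9 and ARO10, for aromatic amino acid breakdown, by 4.34 ± 0.24 and 4.27 ± 0.29. SNZ1, for pyridoxine synthesis, rose by 3.08 ± 0.17, and ATR1, an exporter known to give resistance to 3-AT, by 3.24 ± 0.18. Of 14 permease genes under nitrogen catabolite repression, 8 rose (9 adjusted over the list alone, median 1.19, adjusted p = 0.15 with an estimated correlation, 0.032 with median centring). GAP1, the general amino acid permease gene, rose by 1.57 ± 0.34 and the urea transporter gene DUR3 by 2.03 ± 0.26. Neither the proline permease gene PUT4 (0.06 ± 0.37, adjusted p = 0.92) nor the GABA permease gene UGA4 (0.30 ± 0.30, adjusted p = 0.46) passed the test.

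Many ribosomal protein and ribosome biogenesis genes fell with 3-AT in wild type. Of 71 mitochondrial ribosomal protein genes 50 fell (54 adjusted over the list alone, median -0.89, adjusted p = 0.097 with an estimated correlation, 0.043 with quantile normalization, 2.5e-04 with median centring, 0.0022 without the 3 arrays), MRPL31 at -2.11 ± 0.23 and MRPS8 at -2.08 ± 0.22. Among 80 cytosolic ribosomal protein genes 38 fell and 1 rose (44 and 1 adjusted over the list alone, median -0.76, adjusted p = 0.15 with an estimated correlation), and among 82 ribosome biogenesis genes 37 fell (40 adjusted over the list alone, median -0.74, adjusted p = 0.50 with an estimated correlation). CDS1, for phospholipid synthesis (-2.32 ± 0.24), SIL1, an exchange factor of the endoplasmic reticulum (-2.39 ± 0.22), and COX8, a cytochrome oxidase subunit gene (-2.29 ± 0.26), fell too. In all, 2457 of 6869 probe sets passed, 1523 higher and 934 lower (3690 without the 3 arrays). Quantile normalization gave 1193 higher and 1261 lower and moved the median change of all probe sets from 0.09 to -0.08.

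In wild type, rapamycin raised the genes under nitrogen catabolite repression and lowered the ribosomal protein genes. All 14 permease genes under this repression rose (14 adjusted over the list alone, median 3.15, adjusted p = 1.6e-05), among them DIP5 (6.86 ± 0.26), the urea transporter gene DUR3 (4.90 ± 0.25), the ammonium permease gene MEP2 (4.64 ± 0.33), the GABA permease gene UGA4 (4.07 ± 0.30) and GAP1 (4.69 ± 0.34, adjusted p = 1.0e-17). GAP1 signal went from 526 ± 174 to 12838 ± 501 (mean ± SD). Of 15 catabolic enzyme genes 14 rose and 1 fell (14 and 1 adjusted over the list alone, median 2.52, adjusted p = 0.0043), PUT1, for proline oxidation, by 4.66 ± 0.26, the allantoicase gene DAL2 by 4.64 ± 0.25 and the arginase gene CAR1 by 4.56 ± 0.37. ASP1, encoding an asparaginase, was the member that fell (-1.63 ± 0.28). The allantoate permease gene DAL5 rose by 4.47 ± 0.20, and of its other probe sets one read 4.40 and the dimmest 0.83 (adjusted p = 0.42). The vacuolar carboxypeptidase gene CPS1 rose by 3.75 ± 0.28.

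Of 80 cytosolic ribosomal protein genes 78 fell with rapamycin (78 adjusted over the list alone, median -2.61, adjusted p = 1.6e-05). RPS26B (-5.17 ± 0.57), RPS7A (-4.71 ± 0.50) and RPL9A (-4.28 ± 0.35) were among those that fell furthest, and RPL3 signal went from 11046 ± 1022 to 2206 ± 613 (mean ± SD). RPL15B (-0.10 ± 0.23, adjusted p = 0.78) and RPL10 (-0.89 ± 0.45, adjusted p = 0.11, 9.8e-08 without the 3 arrays) did not pass. Ribosome biogenesis genes fell on 79 of 82 members (80 adjusted over the list alone, median -1.81, adjusted p = 0.062 with an estimated correlation, 7.7e-04 with the replicate block, 0.048 with median centring), among them the helicase gene DBP2 (-3.95 ± 0.32) and the nucleolar protein gene NSR1 (-1.72 ± 0.47). RNA polymerase I and III subunit genes fell on 16 of 19 (16 adjusted over the list alone, median -1.32, adjusted p = 0.10 with an estimated correlation, 0.048 with median centring), RPA190 at -2.31 ± 0.28.

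Of 21 histidine, arginine and lysine genes 14 rose with rapamycin in wild type (15 adjusted over the list alone, median 1.16, adjusted p = 0.015), ORT1 by 2.68 ± 0.18 and ARG1 by 1.23 ± 0.31, while ARG3 did not pass (-0.23 ± 0.23, adjusted p = 0.47). Of 26 autophagy genes 17 rose (19 adjusted over the list alone, median 1.06, adjusted p = 0.10 with an estimated correlation, 0.028 with the replicate block, 0.038 with median centring), ATG8, which marks autophagosomes, by 1.90 ± 0.27. The 4 ammonia assimilation genes rose (4 adjusted over the list alone, median 1.62, adjusted p = 0.10 with an estimated correlation, 0.040 with quantile normalization, 0.048 with median centring, 0.014 without the 3 arrays), GLN1, encoding glutamine synthetase, by 1.49 ± 0.42. CIT2, the citrate synthase gene that reports retrograde signalling, rose by 1.04 ± 0.20. Of 24 G1/S cell cycle genes 16 fell (16 adjusted over the list alone, median -0.78, adjusted p = 0.11 with an estimated correlation, 0.048 with median centring), RNR1, a ribonucleotide reductase gene, at -2.74 ± 0.29. CTT1 (0.30 ± 0.27, adjusted p = 0.41) and HSP12 (-0.02 ± 0.28, adjusted p = 0.97), of general stress, did not pass, nor did that list, though many members rose (median 0.71). In all, 2597 probe sets passed, 1522 higher and 1075 lower (1275 and 1336 with median centring; 3763 without the 3 arrays).

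Set against each other in wild type, 3-AT gave higher sulfur assimilation and ribosomal protein mRNA, and rapamycin gave higher mRNA of genes under nitrogen catabolite repression. Permease genes were lower with 3-AT on 12 of 14 members (13 adjusted over the list alone, median -2.26, adjusted p = 4.9e-04) and catabolic enzyme genes on 11 of 15 (12 adjusted over the list alone, median -1.64, adjusted p = 0.014; adjusted p = 0.15 with probe sets above background on all arrays). UGA4 (-3.77 ± 0.30), PUT1 (-4.02 ± 0.26) and GDH3, encoding a glutamate dehydrogenase (-4.60 ± 0.40), were lower with 3-AT. Cytosolic ribosomal protein genes were higher with 3-AT on 75 of 80 (77 adjusted over the list alone, median 1.81, adjusted p = 0.0016). Sulfur genes were higher on 21 of 24 and lower on 1 (22 and 1 adjusted over the list alone, median 2.10, adjusted p = 0.0054), SUL2 by 4.08 ± 0.35, and histidine, arginine and lysine genes on 13 of 21 (14 adjusted over the list alone, median 0.70, adjusted p = 0.014). In total 2439 probe sets differed, 1358 higher and 1081 lower (1210 and 1246 with quantile normalization; 3553 without the 3 arrays).

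Many probe sets moved the same way with both drugs in wild type. Of the probe sets that passed, 819 rose and 448 fell with both, and 96 went in opposite directions. Independent calls would share 337 rises and 146 falls. The 4 untreated arrays serve both comparisons. In 100 simulations of unchanged groups against them, which leave little to call, no calls were shared. The mean covariance of changes was 0.0369 (observed 0.486) and the mean correlation 0.494. With the untreated arrays split between the drugs in 6 ways, 723 to 824 calls were shared, the mean covariance was 0.453 and the mean correlation 0.500, against 0.555 with all 4. Counting only changes of at least 2-fold left 548 shared calls, and leaving out the 3 arrays gave 2090.

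Within the single mutants, 3-AT raised DIP5 by 5.43 ± 0.26 in gcn2, 5.45 ± 0.26 in gcn4 and 3.70 ± 0.26 in gln3, and MET2 by 5.17 ± 0.58 in gcn2 and 6.35 ± 0.58 in gcn4. Of 21 histidine, arginine and lysine genes, 21 rose in gln3 (median 2.11, adjusted p = 1.5e-06), 6 in gcn2, 9 in gcn4 and 4 and 4 in gcn2 gln3 and gcn4 gln3 (21, 6, 9, 4 and 4 adjusted over the list alone), and the list did not pass in those 4 (adjusted p = 0.67 to 0.90 with an estimated correlation). Of 19 heat shock protein folding genes, 12 rose in gcn2, 13 in gcn4 and 7 in gln3, against 5 in wild type (13, 14, 8 and 5 adjusted over the list alone). That list passed in none of these strains (adjusted p = 0.37, 0.15, 0.92 and 0.96 with an estimated correlation; in gcn4 0.025 with median centring and 0.045 without the 3 arrays). COX17, a copper chaperone gene for cytochrome oxidase, fell in gcn2 (-2.94 ± 0.32) and in gcn4 (-2.99 ± 0.32). The number that passed was 2636 in gcn2 (1741 higher and 895 lower; 1217 and 1286 with quantile normalization, 1465 and 1201 with median centring), and 3092 in gcn4 (2020 and 1072; 1424 and 1564, 1624 and 1488). It was 2107 in gln3 (1473 and 634; 987 and 856, 1120 and 1079), 2694 in gcn2 gln3 (1915 and 779; 1226 and 1095, 1473 and 1203) and 2892 in gcn4 gln3 (1957 and 935; 1325 and 1341, 1668 and 1263). Without the 3 arrays the 5 counts were 3830, 4275, 3331, 3625 and 4106.

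The mutants' own responses to rapamycin all held a DIP5 rise and a fall of ribosomal protein genes. DIP5 rose by 6.67 ± 0.26 in gcn2, 6.84 ± 0.26 in gcn4, 6.95 ± 0.26 in gln3, 5.59 ± 0.26 in gcn2 gln3 and 5.72 ± 0.26 in gcn4 gln3. Permease genes rose on 14 of 14 members in gcn2 and gcn4, 11 in gln3 and 10 in each double mutant (14, 14, 11, 11 and 10 adjusted over the list alone, medians 2.99, 2.72, 1.45, 1.33 and 1.46). Cytosolic ribosomal protein genes fell on 78 of 80 in gcn2, 78 in gcn4, 77 in gln3, 74 in gcn2 gln3 and 70 in gcn4 gln3 (78, 78, 78, 76 and 71 adjusted over the list alone, medians -2.19, -2.19, -1.87, -1.62 and -1.97). Both lists passed in all 5 strains (adjusted p of 0.0099 or less; with probe sets above background on all arrays 0.13 for permeases in gcn4 gln3). Counts were 2013 in gcn2 (1204 higher and 809 lower; 950 and 1007 with quantile normalization, 886 and 1101 with median centring), 2385 in gcn4 (1570 and 815; 1138 and 1057, 1050 and 1223) and 2153 in gln3 (1453 and 700; 1025 and 859, 948 and 1143). They were 1854 in gcn2 gln3 (1136 and 718; 776 and 1029 with median centring) and 2959 in gcn4 gln3 (1583 and 1376; 1358 and 1557 with quantile normalization, 168 with only the arrays compared). Without the 3 arrays they were 3258, 3622, 3374, 2812 and 3070, and in gcn4 gln3 1928 probe sets were called with and without them.

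**Figure D1:**
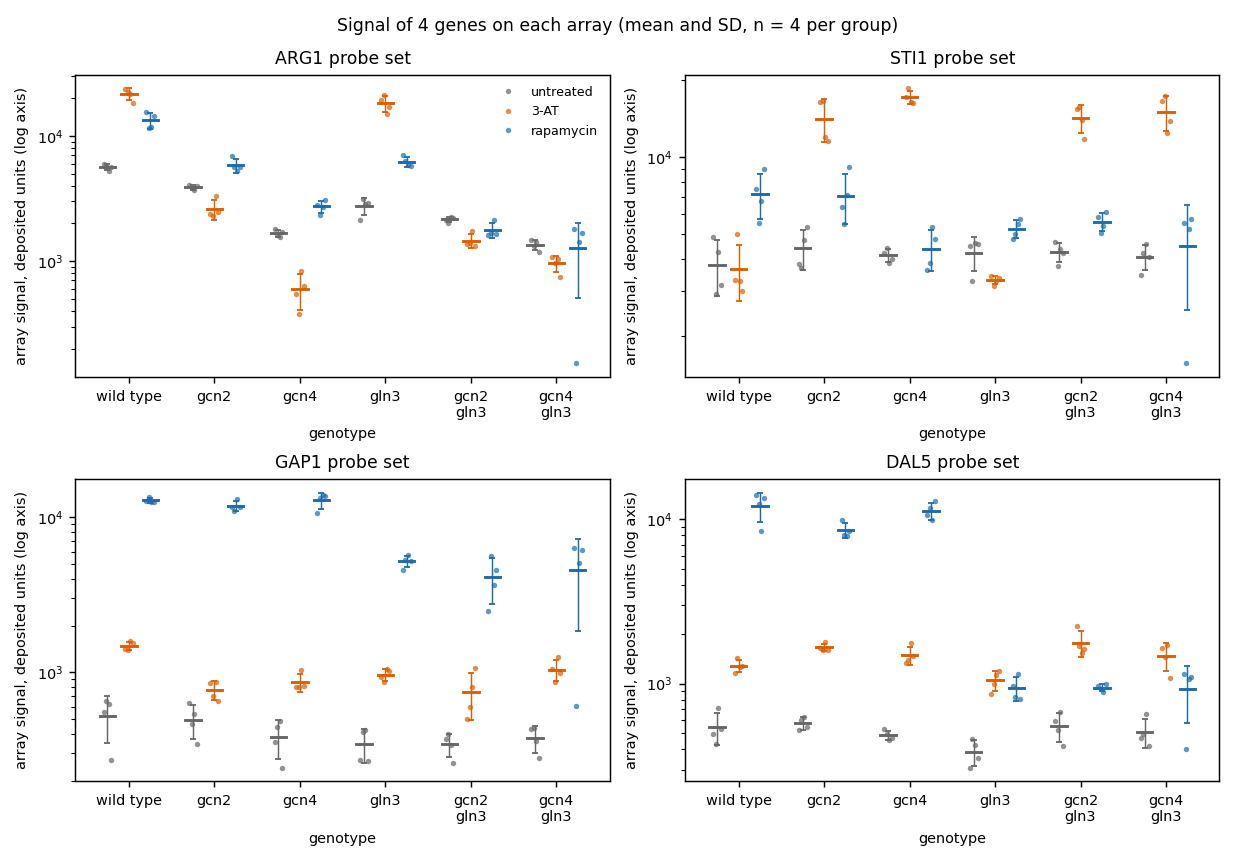
Signal of ARG1, STI1, GAP1 and DAL5 on each array by genotype and treatment, on a log axis, with the mean and standard deviation of each group of 4.

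In gcn2, 3-AT raised amino acid biosynthesis genes less than in wild type, and heat shock genes more. The response of histidine, arginine and lysine genes was lower than in wild type on 13 of 21 members (18 adjusted over the list alone, median -1.76, adjusted p = 9.4e-12), among them ORT1 (-2.90 ± 0.26) and ARG1 (-2.53 ± 0.45, adjusted p = 4.1e-05). TRP4, of tryptophan synthesis (-2.63 ± 0.37), and the asparagine synthetase gene ASN1 (-2.94 ± 0.29) were lower too. ARG1 signal was 3881 ± 151 untreated and 2596 ± 470 with 3-AT in gcn2 (mean ± SD). So were SNO1, for pyridoxine synthesis (-3.54 ± 0.25), and PCL5, a cyclin that promotes Gcn4 turnover (-3.01 ± 0.28). Aromatic genes were lower on 6 of 13 (8 adjusted over the list alone, median -1.25, adjusted p = 0.0014), branched-chain genes on 6 of 10 (9; -1.40, adjusted p = 0.0036), regulators on 6 of 22 (10; -0.37, adjusted p = 0.0014) and vitamin and cofactor genes on 4 of 13 (4; -0.68, adjusted p = 0.0036). HIS4 did not pass (-0.74 ± 0.67, adjusted p = 0.94). Of 19 heat shock protein folding genes 7 were higher (14 adjusted over the list alone, median 1.01, adjusted p = 0.0025), among them the Hsp90 gene HSP82 (1.67 ± 0.42), its cochaperone gene STI1 (1.74 ± 0.31) and the disaggregase gene HSP104 (1.36 ± 0.28). Altogether 235 probe sets responded differently, 51 higher and 184 lower (610 without the 3 arrays).

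In gcn4 too, 3-AT raised amino acid biosynthesis genes less than in wild type, and heat shock genes more. Histidine, arginine and lysine genes were lower on 15 of 21 (16 adjusted over the list alone, median -1.56, adjusted p = 7.4e-10), among them ARG1 (-3.46 ± 0.44, adjusted p = 3.3e-08). SNO1 (-3.54 ± 0.25) and ASN1 (-3.21 ± 0.29) were lower too. ARG1 signal was 1667 ± 108 untreated and 600 ± 191 with 3-AT in gcn4 (mean ± SD). Aromatic genes were lower on 7 of 13 (11 adjusted over the list alone, median -1.35, adjusted p = 0.0017), regulators on 6 of 22 (9; -0.32, adjusted p = 0.0050) and vitamin and cofactor genes on 4 of 13 with 1 higher (8 and 1; -1.51, adjusted p = 0.0098). Branched-chain genes were lower on 5 of 10 (8 adjusted over the list alone, median -1.48, adjusted p = 0.0067; 0.056 with probe sets above background on all arrays). Aspartate family, serine and glycine genes were lower on 6 of 17 (6 adjusted over the list alone, median -0.70, adjusted p = 0.043). Heat shock protein folding genes were higher on 13 of 19 (14 adjusted over the list alone, median 1.40, adjusted p = 7.3e-04): STI1 by 2.11 ± 0.31 (adjusted p = 1.0e-06), HSP82 by 2.32 ± 0.42, HSP104 by 1.84 ± 0.28 and the Hsp40 gene SIS1 by 1.79 ± 0.25. STI1 signal was 3801 ± 928 and 3644 ± 903 in wild type, and 4127 ± 241 and 17067 ± 1037 in gcn4 (mean ± SD). BTN2 and CUR1, which sequester misfolded proteins, were higher by 3.90 ± 0.58 and 3.41 ± 0.55, while the Hsp70 gene SSA1 was not (0.05 ± 0.47, adjusted p = 0.99). In gcn4 387 probe sets differed, 177 higher and 210 lower (991 without the 3 arrays).

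**Figure D2:**
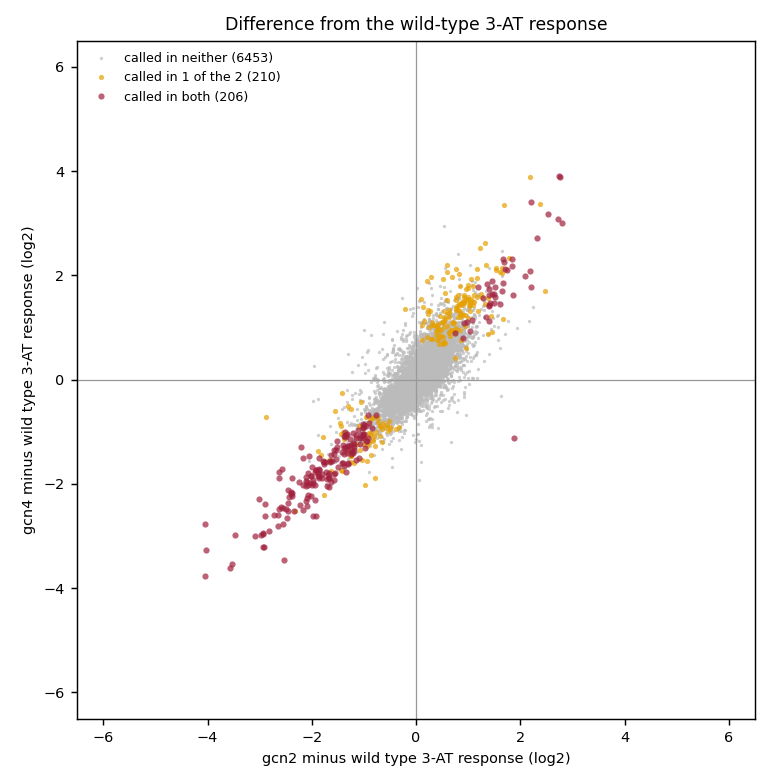
Difference from the wild-type 3-AT response (log2) of each probe set in gcn2 against that in gcn4, marked by whether it passed in both strains (206 probe sets), in 1 of the 2 (210) or in neither (6453).

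Most differences in gcn2 were also found in gcn4: 42 probe sets were higher and 163 lower in both, and 1 went in opposite directions. Independent calls would share 1.31 and 5.63. The wild-type arrays serve both comparisons, and 100 simulations of unchanged groups shared no calls, with a mean covariance of 0.0724 (observed 0.293) and correlation of 0.487. With the wild-type arrays split between the strains in 6 ways, 107 to 119 calls were shared, with a mean covariance of 0.242 and a mean correlation of 0.599, against 0.830 with all. Counting only differences of at least 2-fold left 185 shared calls, and leaving out the 3 arrays gave 497. Compared with each other, the gcn2 and gcn4 responses to 3-AT differed in ARO10 and TAT1. Both lay below background on all untreated and 3-AT arrays of gcn2, so no size is given. These were the 2 probe sets that passed (25 without the 3 arrays).

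In gln3, few genes responded to 3-AT differently from wild type. ROX1, a hypoxic gene repressor, responded less (-1.83 ± 0.37, adjusted p = 0.0095), as did KAR4, a mating and meiosis activator (-1.19 ± 0.24, adjusted p = 0.0095). So did pheromone-regulated PRM10, from a higher untreated level (-1.44 ± 0.26, adjusted p = 0.0034). ARG1 (0.79 ± 0.45, adjusted p = 0.047 without the 3 arrays), HIS4 (-0.12 ± 0.67), GAP1 (-0.06 ± 0.48) and STI1 (-0.29 ± 0.31) did not pass, and no list passed, with heat shock genes at a median of 0.14. Deleted GLN3 was the 4th of 4 passing probe sets, all lower (56 without the 3 arrays; 2 higher and 7 lower with quantile normalization, 2 and 6 with median centring). ROX1 no longer passed without replicate 1 of untreated gln3 (adjusted p = 0.087), nor KAR4 without replicate 4 of untreated wild type (0.086) or replicate 3 of wild type with 3-AT (0.051).

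In gcn2 gln3 and gcn4 gln3, 3-AT raised amino acid biosynthesis and sulfur genes less than in wild type, and heat shock genes more. Histidine, arginine and lysine genes were lower on 14 of 21 in gcn2 gln3 (18 adjusted over the list alone, median -1.78, adjusted p = 5.4e-11) and 14 in gcn4 gln3 (17; -1.85, adjusted p = 9.6e-11). ASN1 was lower too (-2.66 ± 0.29 and -2.86 ± 0.29). Sulfur genes were lower on 9 of 24 in gcn2 gln3 (12 adjusted over the list alone, median -0.87, adjusted p = 0.019) and 12 in gcn4 gln3 (13; -1.34, adjusted p = 8.5e-04), the sulfate permease gene SUL1 at -2.04 ± 0.39 and -3.26 ± 0.39. Heat shock genes were higher on 10 of 19 in gcn2 gln3 (11 adjusted over the list alone, median 0.97, adjusted p = 0.0057) and 9 in gcn4 gln3 (13; 1.15, adjusted p = 0.0031), STI1 by 1.79 ± 0.31 and 1.93 ± 0.31. Aromatic, branched-chain and regulator (deleted GLN3 included) lists were lower in both (medians -1.36, -1.93 and -0.50 in gcn2 gln3, -1.48, -1.49 and -0.44 in gcn4 gln3, adjusted p at most 0.0059). ADR1 and ADH2, a regulator and an enzyme of ethanol use, were higher in gcn4 gln3 by 3.28 ± 0.57 and 2.41 ± 0.34, and 5 G2/M genes passed adjusted over the list alone (4 of 15 over all genes, lower; median -0.69, adjusted p = 0.024). The counts were 340 in gcn2 gln3 (144 higher and 196 lower; 716 without the 3 arrays, of which replicate 1 of gcn2 gln3 with 3-AT is in this comparison) and 382 in gcn4 gln3 (162 and 220; 1038).

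Whether losing GCN4 and GLN3 together changed the 3-AT response by more or less than the sum of the single losses was tested as an interaction. PRM10 passed (2.34 ± 0.37, adjusted p = 3.0e-04) as the single probe set called (53 without the 3 arrays; 3 higher and 1 lower with median centring). The sulfur list (median -0.88, adjusted p = 0.038; 7 members adjusted over the list alone; 0.16 with fry) and the G1/S list (median -0.90, adjusted p = 0.038; 2 members adjusted over the list alone; 0.063 without the 3 arrays) were lower.

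**Figure D3:**
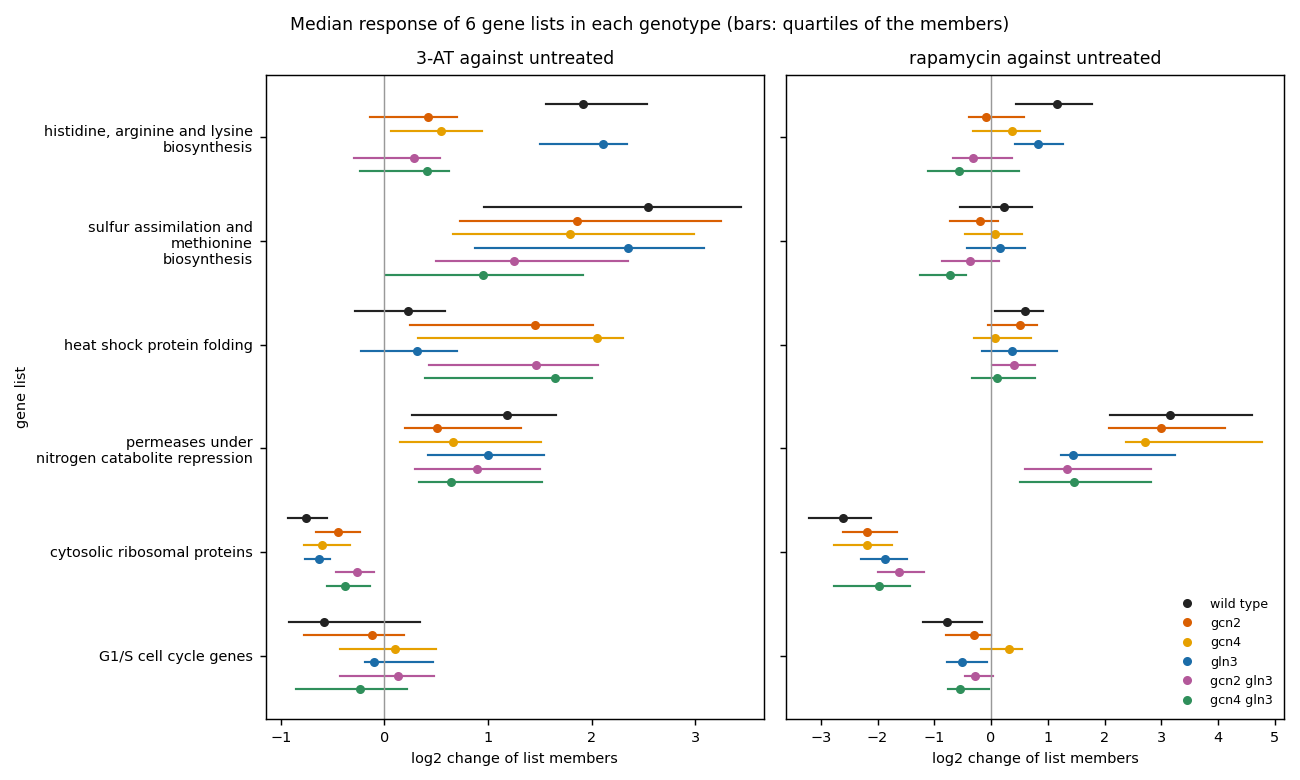
Median and quartiles of the log2 changes with 3-AT and with rapamycin in each genotype for 6 gene lists: histidine, arginine and lysine biosynthesis, sulfur assimilation, heat shock protein folding, permeases, cytosolic ribosomal proteins and G1/S genes.

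In gcn2 and gcn4, histidine, arginine, lysine and aromatic biosynthesis genes had lower responses to rapamycin than in wild type. The median change of the histidine, arginine and lysine list was -0.09 in gcn2 and 0.36 in gcn4, against 1.16 in wild type. The permease list did not pass as a difference (median -0.20, adjusted p = 0.45 in gcn2 and -0.01, adjusted p = 0.94 in gcn4, with an estimated correlation). Histidine, arginine and lysine genes were lower on 9 of 21 in gcn2 (10 adjusted over the list alone, median -1.13, adjusted p = 2.2e-11) and 8 in gcn4 (13; -1.11, adjusted p = 1.9e-08), with ARG3, encoding ornithine carbamoyltransferase, at -2.03 ± 0.33 in gcn2. In gcn4 with rapamycin ARG3 lay below background, at least 4.24-fold lower than without. ADH5, encoding an alcohol dehydrogenase (-2.56 ± 0.27 and -2.45 ± 0.27), and TMT1, encoding a methyltransferase (-2.38 ± 0.35 and -2.52 ± 0.35), were lower. Aromatic genes were lower on 5 of 13 in gcn2 (5 adjusted over the list alone, median -0.89, adjusted p = 0.0048) and 4 in gcn4 (8; -0.99, adjusted p = 0.0045), and the regulator list was lower in gcn2 (1 of 22, 1 adjusted over the list alone; -0.29, adjusted p = 0.0037). Branched-chain genes were lower in gcn4 on 1 of 10 (3 adjusted over the list alone, median -0.90, adjusted p = 0.015; 0.15 with probe sets above background on all arrays). GAP1 (-0.07 ± 0.48 in gcn2, 0.43 ± 0.48 in gcn4) and DAL5 (-0.57 ± 0.28, 0.06 ± 0.28) did not pass. The count was 52 in gcn2 (5 higher and 47 lower; 134 without the 3 arrays) and 73 in gcn4 (28 and 45; 278; 14 and 55 with quantile normalization, 22 and 66 with median centring). Of these 2 were higher and 38 lower in both strains, against 0.0204 and 0.308 for independent calls. In 100 simulations of unchanged groups no calls were shared, with a mean covariance of 0.0750 against 0.105 observed. With the wild-type arrays split between the strains, 15 to 20 were shared, with a mean covariance of 0.0679.

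With rapamycin the G1/S cell cycle list had a median change of -0.78 in wild type and 0.32 in gcn4. The response was higher in gcn4 than in wild type on 8 of 24 members (17 adjusted over the list alone, median 0.90, adjusted p = 9.9e-05). RNR1 differed by 2.25 ± 0.41 (adjusted p = 3.4e-04) and POL30, encoding the replication clamp, by 1.71 ± 0.38 (adjusted p = 0.0070). RNR1 signal was 4229 ± 995 untreated and 647 ± 202 with rapamycin in wild type, and 4339 ± 948 and 3064 ± 508 in gcn4 (mean ± SD). HO, the mating type switching endonuclease gene, was higher in gcn4 by 2.77 ± 0.34. Compared with each other, the gcn2 and gcn4 responses to rapamycin differed in HO (-2.00 ± 0.34 in gcn2 against gcn4, adjusted p = 5.6e-04) and in the G1/S list (median -0.55, adjusted p = 0.0053; 8 members adjusted over the list alone). That comparison called 3 probe sets, 1 higher and 2 lower (10 with the replicate block, 22 without the 3 arrays; 3 and 2 with quantile normalization, 4 and 2 with median centring).

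In gln3, rapamycin raised a subset of the genes under nitrogen catabolite repression less than in wild type. These included DAL5 (-3.18 ± 0.28, adjusted p = 1.9e-12), the allantoicase gene DAL2 (-2.42 ± 0.35), and CPS1 (-2.68 ± 0.39). The peptide transporter genes OPT2 (-3.04 ± 0.46) and PTR2 (-2.71 ± 0.58) were lower too. DAL5 signal was 543 ± 121 and 12045 ± 2459 in wild type, and 385 ± 67.8 and 937 ± 154 in gln3 (mean ± SD), and its other probe sets read -3.60 and, for the dimmest, -0.16. Permease genes were lower on 4 of 14 (7 adjusted over the list alone, median -0.81, adjusted p = 5.1e-05) and catabolic enzyme genes on 3 of 15 (8; -0.96, adjusted p = 0.0045). GAP1 (-0.74 ± 0.48, adjusted p = 0.92), MEP2 (-1.12 ± 0.47, adjusted p = 0.49, 0.0055 without the 3 arrays) and DUR3 (-0.88 ± 0.36, adjusted p = 0.45) did not pass. Cytosolic ribosomal protein genes fell less in gln3, 4 of 80 passing (14 adjusted over the list alone, 26 over all genes without the 3 arrays; median 0.71, adjusted p = 0.016), RPS9A by 1.89 ± 0.36. The response of CIT2, whose untreated level was lower in gln3 than in wild type, was higher by 1.67 ± 0.29 (adjusted p = 3.2e-04). That of MTD1, a one-carbon enzyme gene, was higher by 2.33 ± 0.42.

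Regulator genes were lower on 3 of 22 in gln3 with rapamycin (3 adjusted over the list alone, median -0.10, adjusted p = 0.027; 0.074 with fry, and 0.25 with probe sets above background on all arrays, which leaves out the deleted GLN3), and histidine, arginine and lysine genes at a median of -0.41 (adjusted p = 0.014; 0.068 with fry; 2 members adjusted over the list alone). Of 14 purine and one-carbon genes 4 were higher (6 adjusted over the list alone, median 0.89, adjusted p = 0.067 with an estimated correlation, 0.033 with quantile normalization, 0.019 with median centring, 0.0014 without the 3 arrays). In gln3 62 probe sets differed with rapamycin, 35 higher and 27 lower (304 without the 3 arrays, 120 with the replicate block; 27 and 40 with median centring). Leaving out any 1 of the arrays compared gave 34 to 61, with 34 without replicate 1 of gln3 with rapamycin.

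In gcn2 gln3 and gcn4 gln3, both the amino acid biosynthesis genes and the genes under nitrogen catabolite repression had lower responses to rapamycin than in wild type. The median change of the histidine, arginine and lysine list was -0.31 in gcn2 gln3 and -0.57 in gcn4 gln3, against 1.16 in wild type. Histidine, arginine and lysine genes were lower on 12 of 21 in gcn2 gln3 (17 adjusted over the list alone, median -1.30, adjusted p = 1.8e-09) and 16 in gcn4 gln3 (18; -1.70, adjusted p = 1.1e-06), ORT1 at -2.31 ± 0.26 and -1.85 ± 0.26. Permease genes were lower on 8 of 14 in gcn2 gln3 (11 adjusted over the list alone, median -1.25, adjusted p = 4.9e-06) and 7 in gcn4 gln3 (13; -1.39, adjusted p = 0.0011), MEP2 at -1.93 ± 0.47 and -2.50 ± 0.47 (-1.65 in gcn4 gln3 without the 3 arrays). CPS1 was lower as well (-2.35 ± 0.39 and -2.35 ± 0.39). Catabolic enzyme genes were lower on 5 of 15 (7 adjusted over the list alone, median -1.07, adjusted p = 0.0019) and 7 (9; -1.30, adjusted p = 0.0099). GAP1 did not pass in either (-1.16 ± 0.48, adjusted p = 0.28, 0.035 without the 3 arrays, and -1.53 ± 0.48, adjusted p = 0.055, 0.027 with quantile normalization, but -0.72 and 0.16 without the 3 arrays). Cytosolic ribosomal protein genes fell less in gcn2 gln3, 22 of 80 passing (40 adjusted over the list alone, median 0.99, adjusted p = 0.0019), RPS9A by 2.74 ± 0.36. In gcn4 gln3 23 of 80 passed (37 adjusted over the list alone, median 0.56, adjusted p = 0.054 with an estimated correlation, 0.028 with quantile normalization; without the 3 arrays, of which 1 is in this comparison, the median was 0.93, adjusted p = 0.0093).

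Aromatic, branched-chain and regulator (deleted GLN3 included) lists were lower in both double mutants with rapamycin (medians -1.38, -1.27 and -0.30 in gcn2 gln3, -1.43, -1.49 and -0.59 in gcn4 gln3). With probe sets above background on all arrays the branched-chain list no longer passed in either (adjusted p = 0.064 and 0.097), nor the regulator list in gcn4 gln3 (0.057). The rapamycin response of CIT2 was higher in gcn4 gln3 by 1.90 ± 0.29, from an untreated level lower than in wild type. Sulfur genes were lower in gcn4 gln3 on 9 of 24 (14 lower and 1 higher adjusted over the list alone, median -0.99, adjusted p = 0.049; 0.057 with probe sets above background on all arrays). In gcn2 gln3 227 probe sets differed, 77 higher and 150 lower (540 without the 3 arrays). In gcn4 gln3 283 differed, 86 higher and 197 lower (477 without the 3 arrays, 32 with only the arrays compared; 180 and 177 with median centring). Leaving out any 1 of the arrays compared gave 218 to 835, highest without replicate 1, 3 or 4 of gcn4 gln3 with rapamycin. With only the arrays compared MEP2 and CPS1 no longer passed (adjusted p = 0.42 and 0.11).

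As an interaction of losing GCN4 and GLN3 in the rapamycin response, MTH1, a regulator of hexose transporter genes, was higher by 2.19 ± 0.46 (adjusted p = 0.015), and HO and the ATP sulfurylase gene MET3 were lower (-3.28 ± 0.48 and -2.46 ± 0.43). In total 9 probe sets passed, 2 higher and 7 lower (55 without the 3 arrays; 3 and 3 with quantile normalization, 9 and 6 with median centring). With only the arrays compared neither MTH1 (adjusted p = 0.072) nor MET3 (0.083) passed, and the median of all probe sets moved from -0.25 to 0.17 with median centring.

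Without treatment, gcn2 cells differed from wild type in few genes. SUL1 was higher by 1.78 ± 0.27 (adjusted p = 1.7e-05) and the aromatic aminotransferase gene ARO9 lower (-1.36 ± 0.24, adjusted p = 2.8e-04). TAT1, an amino acid permease gene, gave a signal of 1415 ± 473 (mean ± SD) in wild type and 12.3 ± 8.66 in gcn2, at least 15.8-fold lower. Whether the gcn2 deletion or another change made with the strain accounts for this was not tested. In all 10 probe sets passed, 5 higher and 5 lower (14 without the 3 arrays). With only the 8 arrays compared neither SUL1 (adjusted p = 0.10) nor ARO9 (0.25) passed.

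In untreated gcn4 some phosphate, amino acid and vitamin genes lay below wild type. PHO84, the high-affinity phosphate transporter gene, was lower (-3.86 ± 0.40), as were the carboxylate transporter gene THI73 (-3.56 ± 0.37), the hexose transporter gene HXT5 (-2.69 ± 0.32) and ARG1 (-1.76 ± 0.31). Phosphate starvation genes were lower on 2 of 14 (2 lower and 1 higher adjusted over the list alone, median -0.30, adjusted p = 7.2e-06), histidine, arginine and lysine genes on 3 of 21 (7; -0.31, adjusted p = 3.0e-04) and vitamin and cofactor genes on 5 of 13 (5; -0.43, adjusted p = 0.0033), SNO1 at -1.32 ± 0.18. The MATalpha-specific list was lower, on 2 of 4 (2 adjusted over the list alone, median -0.76, adjusted p = 0.010; 0.089 with probe sets above background on all arrays), as was the regulator list, of which GCN4 itself passed (median -0.09, adjusted p = 0.010; 0.61 with probe sets above background on all arrays). NFS1, the cysteine desulfurase gene that lies next to LEU2, gave 2810.2 ± 631 in wild type and 16094 ± 1034 in gcn4 (mean ± SD). Altogether 83 probe sets passed, 20 higher and 63 lower (226 without the 3 arrays).

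Untreated gln3 cells had less mRNA of CIT2 (-1.94 ± 0.20, adjusted p = 5.5e-10), of MEP1, an ammonium permease gene (-1.13 ± 0.19), and of DPI8 (-2.27 ± 0.19), a small gene of unknown function. The riboflavin transporter gene MCH5 was higher by 1.31 ± 0.16 and PRM10 by 1.27 ± 0.19. GAP1 (-0.57 ± 0.34, adjusted p = 0.98) and DAL5 (-0.49 ± 0.20, adjusted p = 0.49) did not pass, nor did any list. In all 55 probe sets passed, 12 higher and 43 lower (212 without the 3 arrays; 17 and 31 with quantile normalization; 25 to 50 without any 1 of the 8 arrays compared, lowest without replicate 4 of wild type).

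Untreated gcn2 gln3 and gcn4 gln3 cells had less mRNA of vitamin genes, CIT2 and DPI8 than wild type. The vitamin and cofactor list was lower on 5 of 13 in gcn2 gln3 (7 adjusted over the list alone, median -0.85, adjusted p = 2.4e-04) and 5 in gcn4 gln3 (8; -0.98, adjusted p = 3.0e-05), SNZ1 at -1.77 ± 0.17 and -1.99 ± 0.17 and, in gcn4 gln3, the thiazole synthase gene THI4 at -2.57 ± 0.34. CIT2 (-1.78 ± 0.20 and -1.91 ± 0.20), DPI8 (-2.92 ± 0.19 and -2.91 ± 0.19) and ARG1 (-1.39 ± 0.31 and -2.07 ± 0.31) were lower. TAT1 gave a signal of 11.3 ± 5.32 in gcn2 gln3 and NFS1 16401 ± 1773 in gcn4 gln3 (mean ± SD). The count was 92 in gcn2 gln3 (20 higher and 72 lower; 268 without the 3 arrays, 57 without its untreated replicate 2) and 82 in gcn4 gln3 (19 and 63; 309).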

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

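The tests with 1 array left out were written before the 3 patterns below were seen, and the tests of scaling, of the losses of GCN2, GCN4 and GLN3, and of other splits of the arrays were chosen only after.

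Heat shock protein folding genes responded more to 3-AT in gcn4 than in wild type, by a median of 1.40 ± 0.30 over 19 genes. Standard errors here are over genes and hold no array spread. Under the 2 other scalings the lower median was 1.33, and leaving out any of the 16 arrays left at least 1.34, both above 0.70, which is 0.5 times the value. That argues against a scaling or a single array. The median was 1.01 ± 0.22 in gcn2, 0.97 ± 0.19 in gcn2 gln3, 1.15 ± 0.22 in gcn4 gln3 and 0.14 ± 0.11 in gln3, so loss of the Gcn2-Gcn4 branch may be the cause. Whether these cells meet unfolded protein, or grow in a way that raises heat shock factor activity, stays open, since nothing but mRNA was measured.

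Cytosolic ribosomal protein genes fell less with rapamycin in gln3 than in wild type, by a median of 0.71 ± 0.053 over 80 genes. The lower median under the 2 other scalings was 0.61 and the lowest with 1 array left out was 0.61, both above 0.36, which argues against a scaling or a single array. The 50 genes whose probe set carries no mark of shared sequence gave 0.71 as well. If loss of GLN3 were the cause, gcn2 gln3 should exceed gcn2 and gcn4 gln3 exceed gcn4, and the medians were 0.54 ± 0.049 and 0.12 ± 0.11 with all arrays, and 0.54 ± 0.042 and 0.55 ± 0.042 without the 3 arrays. The result thus turns on 1 outlying array and stays open, and the limit for this last test was set to 0.5 times the value, as in the other patterns, after its medians had been seen.

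The rapamycin response of G1/S cell cycle genes was higher in gcn4 than in wild type, by a median of 0.90 ± 0.15 over 24 genes. The lower median under the 2 other scalings was 0.80 and the lowest with 1 array left out was 0.84, both above 0.45, which argues against a scaling or a single array. In gcn4 gln3 the median was 0.40 ± 0.14 with all arrays and 0.44 ± 0.12 without the 3 arrays. Those values lie within 1 standard error of 0.45, so whether loss of GCN4 is the cause stays open.

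Splits of the same arrays into groups of the same sizes ask if random grouping calls as many probe sets. For 9 direct comparisons, taken as unpaired, only the real split of 35 called as many. If unpaired, that argues against chance in all but 1. The real count and the highest other with 3-AT were 2457 and 583 in wild type, 2636 and 352 in gcn2 and 2892 and 653 in gcn4 gln3, and for 3-AT against rapamycin in wild type 2439 and 477. Without treatment they were 83 and 16 for gcn4, 55 and 19 for gln3, 92 and 13 for gcn2 gln3 and 82 and 19 for gcn4 gln3. In gcn4 gln3 with rapamycin they were 2959 and 2625 (median of others 1180), so the 8 arrays hold structure beyond the treatment and chance stays open.

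In the other 9 the data pair the arrays by number, and 8 splits, the real one included, part all pairs, too few for a share under 0.05. With 3-AT the real count and the highest other of these were 3092 and 462 in gcn4, 2107 and 140 in gln3 and 2694 and 395 in gcn2 gln3. With rapamycin they were 2597 and 315 in wild type, 2013 and 72 in gcn2, 2385 and 121 in gcn4, 2153 and 17 in gln3 and 1854 and 29 in gcn2 gln3, and for untreated gcn2 10 and 0. Splits that part fewer pairs reached 589, 351 and 1162 with 3-AT, 1039, 489, 512, 444 and 902 with rapamycin, and 1 in untreated gcn2.

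For differences of responses, 100 regroupings were drawn for each, the real one included. With 3-AT, as many probe sets as the real count came from 5 for gcn2 (235, highest other 371), 3 for gcn4 (387, 452), 2 for gln3 (4, 4), 4 for gcn2 gln3 (340, 530) and 4 for gcn4 gln3 (382, 592). With rapamycin it was 4 for gcn2 (52, 89), 4 for gcn4 (73, 305), 3 for gln3 (62, 93), 4 for gcn2 gln3 (227, 708) and 7 for gcn4 gln3 (283, 571). For gcn2 against gcn4 it was 7 with 3-AT (2, 32) and 10 with rapamycin (3, 42), and for the interaction of losing GCN4 and GLN3 it was 7 with 3-AT (1, 273) and 4 with rapamycin (9, 75). At 5 or more of 100, chance cannot be excluded for the count in gcn4 gln3 with rapamycin, gcn2 against gcn4 with 3-AT and the 3-AT interaction. By that limit it is not excluded for gcn2 with 3-AT either, but the 4 others with as many all kept the treated arrays of each genotype together, and so kept the difference between the treated groups. Among regroupings that mix the genotypes of the treated arrays the highest counts for gcn2, gcn4, gln3, gcn2 gln3 and gcn4 gln3 were 11, 108, 4, 54 and 22 with 3-AT and 6, 1, 93, 89 and 571 with rapamycin. They were 30 and 42 for gcn2 against gcn4 with 3-AT and rapamycin, and 273 and 75 for the interaction.

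These regroupings ignore that arrays pair by number. Both responses pair in 5 differences with rapamycin, where 35 splits keep each treated array with its untreated partner, and 1 of the 35, the real one, called as many. The highest other was 1 for gcn2 gln3 and 0 for gcn2, gcn4, gln3 and gcn2 against gcn4. For gcn2 the untreated arrays also pair with those of wild type, and 8 splits part all numbers, too few for a share under 0.05. For gcn2 against gcn4 with rapamycin the 2 kinds of split differ, so whether chance gave its 3 calls stays open.

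An outlier test by group was run on 90 array measures, of which 15 stood out, and on 90 gene levels, of which 6 did, where chance alone picks about 1 in 20 groups. The actin 3'/5' ratio stood out on 9 arrays, 8 of them replicate 1. On replicate 1 it was 4.13 in gcn4 with rapamycin, 3.22 in gln3 with 3-AT, 3.20 in gln3 with rapamycin, 5.03 in untreated gcn2 gln3, 230 in gcn2 gln3 with 3-AT, 113 in gcn2 gln3 with rapamycin, 4.47 in untreated gcn4 gln3 and 2.75 in gcn4 gln3 with 3-AT. On replicate 2 of gcn4 gln3 with rapamycin it was 43.2. The mean signal of the spiked control probe sets on that array was 22673, against 2868 to 3196 on the others of its group. Its mean correlation with all other arrays was 0.542 (others 0.930 to 0.947), and that of replicate 1 of gcn2 gln3 with 3-AT was 0.864 (0.931 to 0.935). Replicate 2 of wild type with rapamycin correlated at 0.934 (0.921 to 0.922). The median signal of replicate 3 of untreated gcn4 was 311 (278 to 282), and the share of signal in the 20 brightest probe sets on replicate 1 of untreated gcn2 gln3 was 6.45% (5.60% to 5.74%).

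GCN2 read 88.5 on replicate 2 of gcn2 gln3 with rapamycin (114 to 118 on the others) and 81.5 on replicate 2 of gcn4 gln3 with rapamycin (262 to 294). GCN4 read 11.3 on replicate 4 of untreated gcn4 gln3 (22.9 to 23.9), and GLN3 read 30.7 on that array (0.870 to 3.08). On replicate 2 of untreated gcn2, GLN3 read 179 (204 to 209). STI1 read 4983 on replicate 2 of wild type with 3-AT (3010 to 3316).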

How the results depend on the processing

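Leaving out the 3 arrays with an actin ratio over 10, and leaving out replicate 2 of gcn4 gln3 with rapamycin where a comparison does not hold it, were tests chosen only after the results were seen, and the other tests were chosen before. A count is said to have moved where it differs from the main value by more than 1.5 times. Nothing that passed, in the results as given or under an alternative, changed direction. Of 181 gene results in the text 153 kept their call and direction under all alternatives and 11 lost the call under at least 1, and of 155 list results 85 kept theirs under all and 22 lost the call under at least 1.

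The spread is pooled over all groups, and leaving out the 3 arrays gave large moves. Without them 28 of 36 counts moved, all upward. For the 3-AT response the count was 3690 in wild type and 3331 in gln3, and for rapamycin 3258 in gcn2, 3622 in gcn4, 3374 in gln3 and 2812 in gcn2 gln3. The difference from wild type with 3-AT was 610 in gcn2, 991 in gcn4, 56 in gln3, 716 in gcn2 gln3 and 1038 in gcn4 gln3, and with rapamycin 134, 278, 304, 540 and 477. Untreated it was 226 in gcn4, 212 in gln3, 268 in gcn2 gln3 and 309 in gcn4 gln3. For gcn2 against gcn4 it was 25 with 3-AT and 22 with rapamycin, and for the interaction of GCN4 and GLN3 53 and 55. The shared calls of 3-AT and rapamycin in wild type were 2090, and of gcn2 and gcn4 497 with 3-AT and 99 with rapamycin. List tests that passed went from 99 to 178.

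Array weights, which count all arrays but give the outlying ones little weight, moved 26 of 32 counts, again upward. The 3-AT response was 3818 in wild type, 4164 in gcn2 and 3881 in gln3, and the rapamycin response 3387 in gcn2, 3997 in gcn4, 3630 in gln3 and 2998 in gcn2 gln3. The difference from wild type with 3-AT was 746 in gcn2, 1243 in gcn4, 108 in gln3, 991 in gcn2 gln3 and 1079 in gcn4 gln3, and with rapamycin 167, 338, 333, 592 and 465. Untreated it was 264 in gcn4, 264 in gln3, 360 in gcn2 gln3 and 304 in gcn4 gln3. For 3-AT against rapamycin in wild type it was 3721, for gcn2 against gcn4 53 with 3-AT and 48 with rapamycin, and for the interaction of GCN4 and GLN3 72 and 33. With these weights HIS4 in gcn2 with 3-AT (adjusted p = 0.044), ARG1 in gln3 with 3-AT (0.037) and DUR3 in gln3 with rapamycin (0.037) passed as differences.

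With the variance taken from only the arrays compared, 15 of 32 counts moved. The 3-AT response in gln3 gave 3228 and the rapamycin response in gcn4 gln3 168, a group that holds 1 of the 3 arrays. The difference from wild type with 3-AT was 504 in gcn2, 913 in gcn4, 27 in gln3 and 800 in gcn4 gln3, and with rapamycin 91 in gcn2, 177 in gcn4, 139 in gln3 and 32 in gcn4 gln3. Untreated gcn2 gln3 gave 59. The gcn2 against gcn4 comparison gave 13 with 3-AT and 9 with rapamycin, and the interaction of GCN4 and GLN3 gave 49 and 1.

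With only probe sets above background on all arrays, 13 of 33 counts moved, all downward or by a few calls. The 3-AT response was 2044 in gcn4, 1783 in gcn2 gln3 and 1871 in gcn4 gln3, and the rapamycin response in gcn4 gln3 1944. The difference from wild type was 2 in gln3 with 3-AT and 41 in gln3 with rapamycin. Untreated it was 1 in gcn2, 46 in gcn4, 38 in gcn2 gln3 and 41 in gcn4 gln3. For gcn2 against gcn4 with 3-AT limma called 0, with 86 at an unadjusted p under 0.05, and 1 with rapamycin, and the interaction of GCN4 and GLN3 with 3-AT gave 2. Of the list results 15 no longer passed under this filter, among them branched-chain genes in gcn4 with 3-AT and permeases in gcn4 gln3 with rapamycin.

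Quantile normalization moved 3 of 36 counts, each small: 9 for gln3 with 3-AT, 2 for the interaction of GCN4 and GLN3 with 3-AT, and 5 for gcn2 against gcn4 with rapamycin. Median centring moved 5 of 33, namely 8, 4 and 6 for the same comparisons, 15 for the interaction with rapamycin, and 167 list tests. Under median centring the phosphate list no longer passed for rapamycin in wild type (adjusted p = 0.061), gcn2 gln3 (0.072) and gcn4 gln3 (0.089). Using 0.5 times the floor gave 2 for the interaction of GCN4 and GLN3 with 3-AT, and so did an intensity trend with a robust prior. No count moved with 2 times the floor or no filter. Counting only changes of at least 2-fold left 548 shared calls of 3-AT and rapamycin in wild type. With a preset correlation of 0.01 camera passed 461 list tests, and fry, which asks whether members change rather than whether they change more than other genes, passed 362.

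A replicate block moved 12 of 33 counts. The difference from wild type with 3-AT was 19 in gln3 and 596 in gcn4 gln3, and with rapamycin 120 in gln3 and 452 in gcn4 gln3. Untreated it was 133 in gcn4, 112 in gln3, 153 in gcn2 gln3 and 154 in gcn4 gln3. For gcn2 against gcn4 it was 8 with 3-AT and 10 with rapamycin, and for the interaction of GCN4 and GLN3 19 and 62. Pairing by number is seen in the data for the gln3 difference and the gcn2 against gcn4 comparison with rapamycin, whose blocked counts stand beside the main ones in the report. In comparisons that the data do not pair the block is a hint only. There the lists for the aspartate family in gcn4 with 3-AT (adjusted p = 0.067), for sulfur in the 3-AT interaction (0.063) and in gcn4 gln3 with rapamycin (0.058), and for phosphate starvation in the gcn4 gln3 response to rapamycin (0.052; 0.057 without the 3 arrays), did not pass with it. Where the data do pair arrays the block moved no other count by more than 1.5 times. With the block the lists for ribosome biogenesis and autophagy passed for rapamycin in wild type, whose arrays pair by number, and the block changed no other call of a list or gene in paired comparisons.

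Leaving out 1 array moved 42 of 429 counts, and the highest count mostly came without replicate 2 of gcn4 gln3 with rapamycin. The difference from wild type with 3-AT ran from 205 to 458 in gcn2, 295 to 769 in gcn4, 3 to 24 in gln3, 276 to 728 in gcn2 gln3 and 316 to 786 in gcn4 gln3. With rapamycin it ran from 44 to 108 in gcn2, 52 to 194 in gcn4, 34 to 182 in gln3, 183 to 477 in gcn2 gln3 and 218 to 835 in gcn4 gln3, the 835 without its replicate 4. Untreated it ran from 60 to 158 in gcn4, 25 to 159 in gln3, 57 to 177 in gcn2 gln3 and 60 to 206 in gcn4 gln3. For gcn2 against gcn4 it ran from 2 to 6 with 3-AT and 2 to 11 with rapamycin, and for the interaction of GCN4 and GLN3 from 1 to 25 with 3-AT and 7 to 25 with rapamycin.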

Other observations

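The list results here come from tests set before the data were examined, and the readings of TAT1, BAP2, NFS1, DPI8 and SPG4 across strains were chosen only after the results were seen.

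With 3-AT in wild type, amino acid pathways other than histidine, arginine and lysine rose in part. Of the branched-chain genes 8 rose of 10 (8 rose adjusted over the list alone, median 1.27, adjusted p = 0.42 with an estimated correlation), of the aromatic genes 9 rose of 13 (9 rose adjusted over the list alone, median 1.01, adjusted p = 0.32 with an estimated correlation), of the aspartate family, serine and glycine genes 6 rose of 17 (6 rose adjusted over the list alone, median 0.44, adjusted p = 0.63 with an estimated correlation), and of the ammonia assimilation genes 1 rose of 4 (1 rose adjusted over the list alone, median 0.83, adjusted p = 0.78 with an estimated correlation). Without the 3 arrays the aromatic and branched-chain lists passed (adjusted p = 0.0022 and 0.049). Of the catabolic enzyme genes under nitrogen catabolite repression 9 rose and 2 fell of 15 (9 rose and 2 fell adjusted over the list alone, median 0.94, adjusted p = 0.44 with an estimated correlation). Among purine and one-carbon genes 4 rose of 14 (4 rose adjusted over the list alone, median 0.52, adjusted p = 0.78 with an estimated correlation), and among vitamin and cofactor genes 3 rose and 4 fell of 13 (3 rose and 5 fell adjusted over the list alone, median 0.16, adjusted p = 0.78 with an estimated correlation). Of the aminoacyl-tRNA synthetase genes 2 rose and 5 fell of 19 (2 rose and 5 fell adjusted over the list alone, median -0.01, adjusted p = 0.78 with an estimated correlation). Protein turnover was mixed: of the vacuolar protease genes 3 rose and 2 fell of 8 (3 rose and 2 fell adjusted over the list alone, median 0.01, adjusted p = 0.83 with an estimated correlation), of the autophagy genes 7 rose and 2 fell of 26 (7 rose and 2 fell adjusted over the list alone, median 0.17, adjusted p = 0.78 with an estimated correlation), and of the proteasome genes 1 rose and 14 fell of 33 (1 rose and 14 fell adjusted over the list alone, median -0.47, adjusted p = 0.50 with an estimated correlation).

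Stress and growth lists were mixed with 3-AT in wild type. Of the general stress genes 9 rose and 3 fell of 36 (9 rose and 3 fell adjusted over the list alone, median 0.18, adjusted p = 0.96 with an estimated correlation), of the oxidative stress genes 9 rose and 3 fell of 24 (9 rose and 4 fell adjusted over the list alone, median 0.54, adjusted p = 0.78 with an estimated correlation), and of the heat shock genes 5 rose and 3 fell of 19 (5 rose and 4 fell adjusted over the list alone, median 0.23, adjusted p = 0.96 with an estimated correlation). Among RNA polymerase I and III subunit genes 6 fell of 19 (1 rose and 9 fell adjusted over the list alone, median -0.50, adjusted p = 0.63 with an estimated correlation), and among retrograde and citrate cycle genes 2 rose and 2 fell of 18 (1 rose and 1 fell adjusted over the list alone, median -0.05, adjusted p = 0.86 with an estimated correlation). Of the G1/S genes 2 rose and 12 fell of 24 (4 rose and 12 fell adjusted over the list alone, median -0.58, adjusted p = 0.50 with an estimated correlation), of the G2/M genes 5 rose of 15 (5 rose adjusted over the list alone, median 0.19, adjusted p = 0.69 with an estimated correlation), and of the histone genes 1 fell of 4 (1 fell adjusted over the list alone, median -0.36, adjusted p = 0.78 with an estimated correlation). In glycolysis 2 fell of 16 (1 fell adjusted over the list alone, median -0.30, adjusted p = 0.78 with an estimated correlation), in the phosphate starvation list 6 rose of 14 (6 rose adjusted over the list alone, median 0.26, adjusted p = 0.53 with an estimated correlation), and in the iron starvation list 7 rose and 4 fell of 19 (8 rose and 4 fell adjusted over the list alone, median 0.41, adjusted p = 0.78 with an estimated correlation). Of the MATa-specific genes 2 rose of 5 (2 rose adjusted over the list alone, median 0.99, adjusted p = 0.63 with an estimated correlation), of the MATalpha-specific genes 2 rose and 1 fell of 4 (2 rose and 1 fell adjusted over the list alone, median 0.22, adjusted p = 0.86 with an estimated correlation), and of the auxotrophic markers 4 rose of 7 (4 rose adjusted over the list alone, median 0.89, adjusted p = 0.63 with an estimated correlation).

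With rapamycin in wild type the phosphate starvation list passed, where 9 rose of 14 (9 rose adjusted over the list alone, median 0.75, adjusted p = 0.015), and so did the regulators of nitrogen and amino acid control, where 10 rose of 22 (10 rose adjusted over the list alone, median 0.42, adjusted p = 0.030). The phosphate list no longer passed with median centring (adjusted p = 0.061), nor the regulators with probe sets above background on all arrays (0.13). Of the general stress genes 16 rose of 36 (18 rose adjusted over the list alone, median 0.71, adjusted p = 0.64 with an estimated correlation), of the oxidative stress genes 12 rose of 24 (13 rose adjusted over the list alone, median 0.70, adjusted p = 0.42 with an estimated correlation), and of the heat shock genes 10 rose of 19 (10 rose adjusted over the list alone, median 0.59, adjusted p = 0.42 with an estimated correlation). Of the mitochondrial ribosomal protein genes 1 rose and 35 fell of 71 (1 rose and 40 fell adjusted over the list alone, median -0.64, adjusted p = 0.22 with an estimated correlation), and of the aminoacyl-tRNA synthetase genes 8 fell of 19 (8 fell adjusted over the list alone, median -0.47, adjusted p = 0.46 with an estimated correlation). Without the 3 arrays the oxidative stress and mitochondrial ribosomal lists passed (adjusted p = 0.011 and 0.031), the latter also with median centring (0.015). Among sulfur genes 6 rose and 5 fell of 24 (6 rose and 5 fell adjusted over the list alone, median 0.23, adjusted p = 0.88 with an estimated correlation), among retrograde and citrate cycle genes 7 rose of 18 (7 rose adjusted over the list alone, median 0.69, adjusted p = 0.42 with an estimated correlation), and among MATa-specific genes 5 rose of 5 (5 rose adjusted over the list alone, median 1.54, adjusted p = 0.16 with an estimated correlation).

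With 3-AT, the iron starvation list of gcn4 against wild type depended on the choice of test. In gcn4 14 rose of 19 (14 rose adjusted over the list alone, median 1.35, adjusted p = 0.38 with an estimated correlation), and the difference from wild type was a median of 0.94 (adjusted p = 0.061 with an estimated correlation, 0.063 with quantile normalization, 0.033 with median centring, 0.043 without the 3 arrays).

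TAT1 lay above background on none of the 24 arrays of the gcn2 and gcn2 gln3 strains, at 12.3 ± 8.66 (mean ± SD) in untreated gcn2. BAP2, the permease gene beside it, responded less to 3-AT in gcn2 (-4.05 ± 0.59). NFS1, beside LEU2, was higher in untreated gcn4 by 2.55 ± 0.41 and in gcn4 gln3 by 2.57 ± 0.41. Whether the named deletions or other changes made with the strains account for the TAT1 and NFS1 levels was not tested. DPI8, lower in the 3 untreated gln3 strains, rose with rapamycin by 4.89 ± 0.19 in gln3, 5.32 ± 0.19 in gcn2 gln3 and 5.37 ± 0.19 in gcn4 gln3. SPG4, a gene of stationary phase, was lower in untreated gcn4 (-2.86 ± 0.31) and gln3 (-2.49 ± 0.31).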
